A study of Homo sapiens with 16 samples.

How the data were processed

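The samples were 16 RNA preparations of MCF7 cells, per the labels 4 biological replicates each of untransfected cells, cells transfected with a scrambled siRNA, and cells transfected with either of 2 siRNA oligos against GPAM. Per the labels' protocols, cells were reverse transfected with 20 nM siRNA, RNA was taken on day 3 and passed an integrity check, and biotin-labelled RNA was made with the Affymetrix IVT Express kit. The labels do not say whether replicates were separate cultures on separate days, so p-values measure the spread between these samples only.

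The authors deposited log2 signals per probe set for each array. RMA, which corrects the background, quantile normalizes the arrays and summarises the probes of a set, is named in the submitters' processing notes. Its version is not given in the sources used here, and neither is a genome build, so no coordinates are printed. The deposited log2 values have nearly equal distributions: the same rank differs between arrays by 0.0612 in the median and by 0.293 at most. RMA compresses changes of dim probe sets toward 0, and quantile normalization assumes that most genes are alike on all arrays. The median log2 fold change over all genes was -0.01, 0.00 and 0.01 for oligo 1 against scrambled, oligo 2 against scrambled and scrambled against untransfected.

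Per array, 41097 probe sets had a single gene symbol in the platform table used here, 1801 had several and 11777 had none there. Of all these, 62 were controls, 6 of them with a single symbol and 56 without. Entrez identifiers of 41043 probe sets matched the RefSeq gene table (assembly GRCh38.p14, used for names only), and 0 symbols needed updating. Probe sets with several symbols or none were not named. Each of 19775 genes was represented by its probe set with the highest mean over all 16 arrays, with no filter on dim probe sets. For 0 of the named genes did another probe set move the opposite way past the threshold.

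Linear models were fitted with limma (version 3.58.1, R 4.3.3; lmFit and eBayes) to all 16 arrays with the 4 groups as terms, and contrasts were called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera (preset inter-gene correlation 0.01, lists of at least 5 measured genes, adjusted over the 29 lists), and again with an estimated correlation and with fry. The lists held 833 genes, of which 752 were measured under a single symbol here. GPAM was also tested with an exact permutation test. The design, the lists and the rule for named genes were fixed before the data were examined. The rule took the GPAM family and, per comparison, the 10 largest rises and falls past the threshold whose 4 arrays per group did not overlap, 12 rising and 12 falling genes for both oligos by the smaller of the changes, and up to 4 members of a list by adjusted p. The genes changed against both controls were named after their values were seen, as were those of the closing observations.

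Replicate numbers came from the labels. Deviations from the group means correlated at over 0.1 in all 4 same-numbered pairs for oligo 1 and scrambled (0.10 to 0.50), oligo 2 and scrambled (0.32 to 0.62), scrambled and untransfected (0.24 to 0.42) and oligo 2 and untransfected (0.13 to 0.40), so the numbers were read as pairing the arrays there. For the oligos against each other they ran from -0.49 to 0.51 and for oligo 1 and untransfected from 0.06 to 0.35, so by this rule the numbers were not read as pairing these. The lowest value of each was that of the arrays numbered 3. Oligo 1 and untransfected fell short only there (0.06, others 0.20 to 0.35). Since the numbers paired each of these groups with scrambled arrays, the rule does not show that they are unpaired. The main fit held no term for the replicate number, so its p-values leave this pairing out. Counts with the replicate number as a block are given as an alternative.

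The procedure was tested on simulated data. With normal noise at each gene's own spread and 200 changed genes among 19775 in a simulated oligo 1 against scrambled comparison, limma recovered 64.2% of log2 changes of 0.5, 96.7% of changes of 1 and 100% of changes of 2, and 3.98% of its calls were false. Noise was independent between genes and arrays, without pairing or arrays that stand apart. These shares therefore need not hold for the real calls. Alternatives covered the replicate block, a filter on dim probe sets, the mean or the most variable probe set of a gene or each probe set by itself, array medians, a second quantile normalization, a trended prior, array weights, stricter thresholds, untransfected cells as the control, and leaving out each array. Leaving out arrays that stood apart, averaging the oligos and leaving GPAM out of its list were added after the data were seen. Comparisons against the same scrambled arrays were set beside 100 simulations of unchanged groups, and each count beside 35 splits of its 8 arrays or 100 drawn assignments. No genome was used, and siRNA sequences were not analysed here. Figures were drawn with matplotlib from the same tables.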

Results

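Gene expression was measured in MCF7, an estrogen receptor-positive luminal breast cancer cell line, after silencing of GPAM. GPAM encodes the mitochondrial glycerol-3-phosphate acyltransferase, which catalyses the first step of glycerolipid synthesis. The 16 arrays fell into 4 groups of 4 biological replicates, numbered 1 to 4 in each group: untransfected cells, cells given a scrambled small interfering RNA (siRNA), and cells given oligo 1 or oligo 2, which are siRNAs against different exons of GPAM. The siRNA concentration was 20 nM, and RNA was collected on day 3. On each array, 41097 probe sets had a single gene symbol here, and these covered 19775 genes. Any pair of arrays correlated at 0.9798 or above over all probe sets, and no columns were identical. With 4 arrays per group, their number limits the precision. On the plot of principal components, the arrays labelled oligo 1 replicate 3 and oligo 2 replicate 3 each lay among the arrays of the other oligo.

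**Figure D1:**
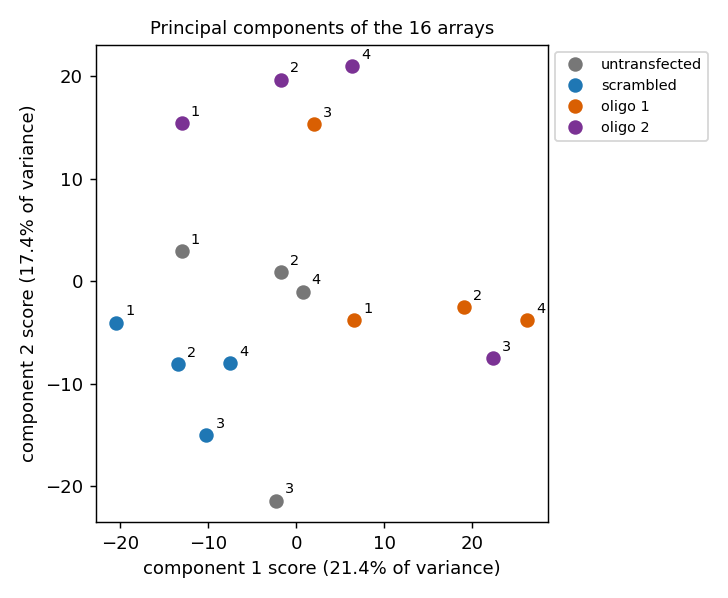
Scores of the 16 arrays on principal components 1 (horizontal, 21.4% of variance) and 2 (vertical, 17.4% of variance), coloured by group, with the replicate number beside each point. On component 2 the array labelled oligo 1 replicate 3 has a score of 15.3, near the oligo 2 arrays 1, 2 and 4 (15.4 to 20.9), and the array labelled oligo 2 replicate 3 has a score of -7.49, near the oligo 1 arrays 1, 2 and 4 (-3.82 to -2.55), while untransfected replicate 3 lies lowest at -21.4.

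GPAM itself was measured first, since both oligos target it. Its brighter probe set read 7.26 ± 0.07 (log2, SD, n = 4) in scrambled arrays, 7.52 ± 0.17 in untransfected arrays, 4.66 ± 0.28 with oligo 1 and 4.74 ± 0.22 with oligo 2. This was 16.4% of the scrambled level with oligo 1 and 17.4% with oligo 2. Both shares are upper limits, as these signals lay below the array medians (5.09 to 5.15), where RMA compresses changes. The log2 fold changes were -2.60 and -2.52 (SE 0.13 for each, limma adjusted p = 1.23e-08 and 2.07e-08). The other probe set gave -2.52 and -2.49. All 8 oligo arrays lay below all 8 control arrays on both probe sets, and the exact two-sided permutation p was 0.0286 for each oligo against scrambled, the smallest that 4 against 4 arrays can give. Against untransfected cells the log2 fold changes were -2.86 and -2.78, and between the controls GPAM differed by -0.26 (SE 0.13, adjusted p = 0.409). The residual level did not differ past the threshold between the oligos (oligo 1 minus oligo 2 -0.08, SE 0.13, adjusted p = 0.989).

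Among the other members of the family, GPAT4 was at 8.05 ± 0.07 in scrambled arrays and differed by 0.08 with oligo 1 and 0.07 with oligo 2 (adjusted p = 0.646 and 0.719). GPAT2 differed by 0.02 and 0.08. GPAT3 was at 6.35 ± 0.31 in scrambled arrays and differed by -1.05 with oligo 1 (SE 0.32, adjusted p = 0.0683) and by -0.50 with oligo 2 (adjusted p = 0.513), neither past the threshold. Without both oligo arrays numbered 3 it was past it with oligo 1 (-1.38, adjusted p = 0.00138) and not with oligo 2 (-0.25, adjusted p = 0.665). With all arrays, GPAT3 was 0.60 higher in scrambled than in untransfected arrays (SE 0.33). Against untransfected arrays it differed by -0.44 with oligo 1 and by 0.10 with oligo 2.

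**Figure D2:**
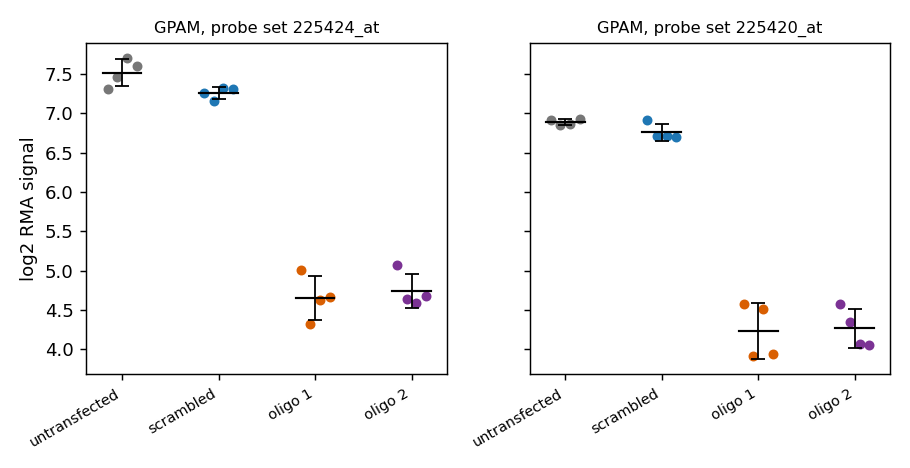
GPAM signal (log2, vertical axis) on each array for both probe sets, by group (horizontal axis), with points for arrays and lines with bars for means ± SD of 4 arrays. All oligo arrays lie below the controls, with group means of 4.66 and 4.74 against 7.26 and 7.52 for the brighter probe set.

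Oligo 1 was compared with the scrambled siRNA to find what changed with GPAM silencing. The genes with the largest rises were KIF3A, a kinesin motor subunit (3.24-fold, log2 fold change 1.70, SE 0.17, adjusted p = 1.82e-05), TMEM87B (3.12-fold), the iron transporter SLC11A2 (3.04-fold), the centromere protein gene CENPK (3.00-fold), TTC9 (2.82-fold), C5orf24 (2.80-fold), SLITRK6 (2.74-fold), SPRING1, a factor needed for sterol-regulated transcription (2.63-fold), the mitotic kinase NEK7 (2.62-fold) and LINC00052 (2.61-fold). After GPAM (6.08-fold lower), the largest falls were in ANXA1, a phospholipid-binding annexin (3.6-fold lower, log2 fold change -1.85, SE 0.45, adjusted p = 0.0211), the desmosomal cadherin DSG2 (3.56-fold), RAB31 (2.98-fold), SYBU (2.82-fold), SYTL5 (2.76-fold), the oxysterol-binding protein gene OSBPL3 (2.74-fold), PAX9 (2.62-fold), the interleukin 1 receptor subunit IL1RAP (2.53-fold) and SEMA6D (2.40-fold). In all, 623 genes were higher and 539 lower of 19775 tested, and 78 of these 1162 changed by a log2 fold change of 1 or more. With the replicate number as a block the count was 1822 (890 higher, 932 lower), and without both oligo arrays numbered 3 it was 1915 (888 higher, 1027 lower). Which direction held more genes thus depended on the setting. The count was 640, 578 and 729 without scrambled replicate 2, 3 or 4, and 654 and 723 without oligo 1 replicate 2 or 4. The calls of ANXA1, RAB31 and SYTL5 were lost when single arrays were left out (for ANXA1 without scrambled replicate 1 or 2 or oligo 1 replicate 2 or 4, for RAB31 without oligo 1 replicate 2 or 4, for SYTL5 without scrambled replicate 1 or 2 or oligo 1 replicate 4). SYTL5 lost its call also with the mean of all probe sets of a gene. By the same rule without both oligo arrays numbered 3, 7 of the 10 largest rises and 7 of the 10 largest falls were the same genes, and H3C2 (1.62, adjusted p = 2.66e-05), SLC26A2 (-1.70, adjusted p = 1.16e-05) and PAPSS2 (-1.64, adjusted p = 0.000223) were among those that entered.

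Oligo 2 was compared with the scrambled siRNA in the same way. TMEM87B rose 3.04-fold (log2 fold change 1.61, SE 0.16, adjusted p = 1.64e-05), CENPK and SLC11A2 3.02-fold each, the phosphoinositide-binding adaptor gene PLEKHA1 2.93-fold, the ETS transcription factor gene ELK4 2.64-fold, the p53-inducible gene TP53INP1 2.63-fold, the kinase gene HIPK3 2.62-fold, SPRING1 and the TGF-beta receptor gene TGFBR1 2.55-fold each, and KIF3A 2.48-fold. GPAM was 5.74-fold lower, and the next falls were in the ephrin receptor gene EPHA7 (2.91-fold lower, log2 fold change -1.54, SE 0.34, adjusted p = 0.0158), RASGRP1 (2.64-fold), GPX8 (2.56-fold), the B-cell linker gene BLNK (2.50-fold), DSG2 (2.46-fold), SEMA6D (2.39-fold), SYBU (2.37-fold), PLAC8 (2.35-fold) and BEX5 (2.34-fold). There were 548 higher and 468 lower genes, 1016 in all, of which 65 had a log2 fold change of 1 or more. The count was 1672 with the replicate block (815 higher, 857 lower) and 1553 without both oligo arrays numbered 3 (732 higher, 821 lower). Here too the direction with more genes depended on the setting. The count was 490, 424 and 568 without scrambled replicate 2, 3 or 4, and 563 and 513 without oligo 2 replicate 2 or 4. The calls of EPHA7, RASGRP1, GPX8, BLNK, DSG2 and SYBU were each lost without scrambled replicate 2 or 3 or oligo 2 replicate 2 or 4 (adjusted p up to 0.138), as were those of RASGRP1, GPX8, DSG2 and SYBU without scrambled replicate 1, and of RASGRP1, DSG2 and SYBU without scrambled replicate 4 or oligo 2 replicate 3. Without both oligo arrays numbered 3, RASGRP1 (adjusted p = 0.0640) and SYBU (adjusted p = 0.0652) lost theirs, and with the mean of all probe sets of a gene EPHA7, RASGRP1 and GPX8 did. By the same rule without both oligo arrays numbered 3, 6 of the 10 largest rises and 4 of the 10 largest falls were the same genes, and TMEM38B (-1.48, adjusted p = 1.48e-05) and ZDHHC4 (-1.39, adjusted p = 7.84e-06) were among those that entered.

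Genes changed by both oligos were counted because independent oligos against the same target serve to tell effects of GPAM loss from those of a single oligo. In this set 411 genes were higher and 278 lower with both oligos, 689 in all, and 0 went in opposite directions. Independent lists of these sizes would share 17.3 higher and 12.8 lower genes. The absence of opposite changes did not hold without both oligo arrays numbered 3. There H3C2 (1.62 with oligo 1 and -0.63 with oligo 2), H2AC6 (0.76 and -0.62) and TGFBI (-0.64 and 0.73), for example, passed the threshold in opposite directions. Beside the genes already named, EFR3A, which anchors a phosphatidylinositol kinase at the plasma membrane, rose 2.30-fold with oligo 1 and 2.28-fold with oligo 2, and the heparan sulfate sulfotransferase gene HS6ST2 rose 2.42- and 2.28-fold. Both oligos also lowered PLAC8 (2.21- and 2.35-fold), the RNA polymerase III subunit gene POLR3G (2.12- and 2.30-fold), FKBP14 (2.00- and 1.99-fold), SPINK7 (2.06- and 1.95-fold) and SYTL4 (1.94- and 2.01-fold). The fold changes of both comparisons correlated at 0.81 across genes, which are not independent replicates. Both share the scrambled arrays: 100 simulations of unchanged groups gave a mean correlation of 0.50 and a highest of 0.89, above the observed one, at most 0 shared calls, and a mean covariance of 0.010 (highest 0.0325) against 0.0390 observed. With the scrambled arrays split 2 and 2, the correlation was 0.54 to 0.68, and 116 to 136 genes were called by both oligos. With oligo 1 against scrambled and oligo 2 against untransfected arrays, the correlation was 0.32 and the covariance 0.0125. The count was 1155 with the replicate block, 583 without both oligo arrays numbered 3, 353, 322 and 411 without scrambled replicate 2, 3 or 4, and 455 without oligo 2 replicate 4. POLR3G lost its call with both oligos without scrambled replicate 3, and with oligo 1 without its replicate 2 or 4. SYTL4 lost its call with both oligos without scrambled replicate 2 or 3, with oligo 1 also without scrambled replicate 1 or oligo 1 replicate 3 or 4, and with oligo 2 without its replicate 4. With the mean of all probe sets of a gene SYTL4 lost its call with both oligos.

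The same genes were then set beside their level in untransfected cells. TMEM87B was at 8.48 ± 0.13 in untransfected arrays, 6.89 ± 0.37 in scrambled arrays, 8.53 ± 0.17 with oligo 1 and 8.49 ± 0.25 with oligo 2 (log2, SD, n = 4 each). Of the 12 leading genes raised by both oligos, 11 were lower in scrambled than in untransfected arrays past the threshold, the exception being HS6ST2 (-0.29, adjusted p = 0.689). Among the lowered genes, PLAC8 read 4.92 to 5.54 in untransfected, 5.82 to 6.14 in scrambled and 4.61 to 5.01 in oligo arrays. For SPINK7 these were 4.19 to 4.92, 4.76 to 5.33 and 3.85 to 4.64. For POLR3G they were 5.74 to 6.71, 6.09 to 6.92 and 4.94 to 5.99. Part of the fall of PLAC8 and SPINK7 thus lay in a higher scrambled level. Of the 689 genes changed by both oligos, 249 (36.1%) had changed the opposite way between scrambled and untransfected cells (196 of the higher and 53 of the lower genes), and 0 had changed the same way. These comparisons share the scrambled arrays with opposite signs, which by itself favours opposite directions. Independent lists of these sizes would give 6.3 higher and 1.9 lower genes of this kind, and in 100 simulations of unchanged groups at most 0 genes were called in all 3 comparisons. The independent lists ignore the shared arrays. The simulations held no changed genes, gave at most 0 shared calls between the oligos as well, and kept the untransfected arrays as their own group. Neither can therefore tell how much the sharing adds to the 249 genes. Against untransfected cells, oligo 1 changed 38 genes (13 higher, 25 lower) and oligo 2 changed 25 (10 higher, 15 lower), with 2531 and 2192 genes at an unadjusted p under 0.05. With the replicate block the counts were 314 for oligo 1 and 202 for oligo 2, and without both oligo arrays numbered 3 they were 813 and 526. Leaving out single arrays gave 8 to 360 genes for oligo 1: 360 and 103 without oligo 1 or oligo 2 replicate 3, 15, 8 and 11 without oligo 1 replicate 1, 2 or 4. It gave 13 and 12 without untransfected replicate 2 or 4, 21 and 23 without scrambled replicate 3 or 4, and 31 to 35 without any other. For oligo 2 it gave 1 to 221: 221 and 51 without oligo 2 or oligo 1 replicate 3, 9, 13 and 1 without oligo 2 replicate 1, 2 or 4. It gave 8, 13 and 2 without untransfected replicate 2, 3 or 4, 13, 15, 10 and 9 without scrambled replicate 1, 2, 3 or 4, 16 without oligo 1 replicate 2 or 4, and 18 and 24 without untransfected or oligo 1 replicate 1. The excess of lower genes did not hold without untransfected replicate 3. There 20 genes were higher and 11 lower with oligo 1, and 7 higher and 6 lower with oligo 2.

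Against both controls, 13 genes changed in the same direction with both oligos. Lower were GPAM, the p21-activated kinase gene PAK2 (log2 fold change against scrambled -0.61 and -0.71), ARHGAP18, a Rho GTPase-activating protein gene (-0.71 and -0.68), the casein kinase gene CSNK1E (-0.31 and -0.32), the endocytic adaptor gene EPS15L1 (-0.80 and -0.69), the helix-loop-helix inhibitor gene ID3 (-0.59 and -0.71), SUDS3, a subunit of the SIN3 corepressor complex (-0.56 and -0.47), the nucleoporin gene POM121C (-0.77 and -0.94), TBC1D30 (-0.72 and -0.68) and the long non-coding RNA LNCAROD (-0.62 and -0.54). Higher were SUZ12, a Polycomb repressive complex subunit (0.45 and 0.44), FAM217B (0.57 and 0.53) and the phosphodiesterase family gene ENPP5 (0.58 and 0.44). With the replicate block 84 genes met these conditions, and 38 without both oligo arrays numbered 3, each including all 13. Leaving out a single array gave 1 to 21 genes: 1 without untransfected replicate 4 or oligo 2 replicate 4, 21 without oligo 2 replicate 3, and 4 to 8 without any other array except untransfected replicate 1 (11), oligo 2 replicate 2 (9) and oligo 1 replicate 3 (17). Against scrambled cells alone, CSNK1E with both oligos and ENPP5 and SUDS3 with oligo 2 lost their calls without single arrays, scrambled replicate 2 among them for each. With the mean of all probe sets of a gene 6 of the 13 remained, and ENPP5, EPS15L1 and SUZ12 were then past the threshold with neither oligo, and PAK2 only with oligo 1.

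**Figure D3:**
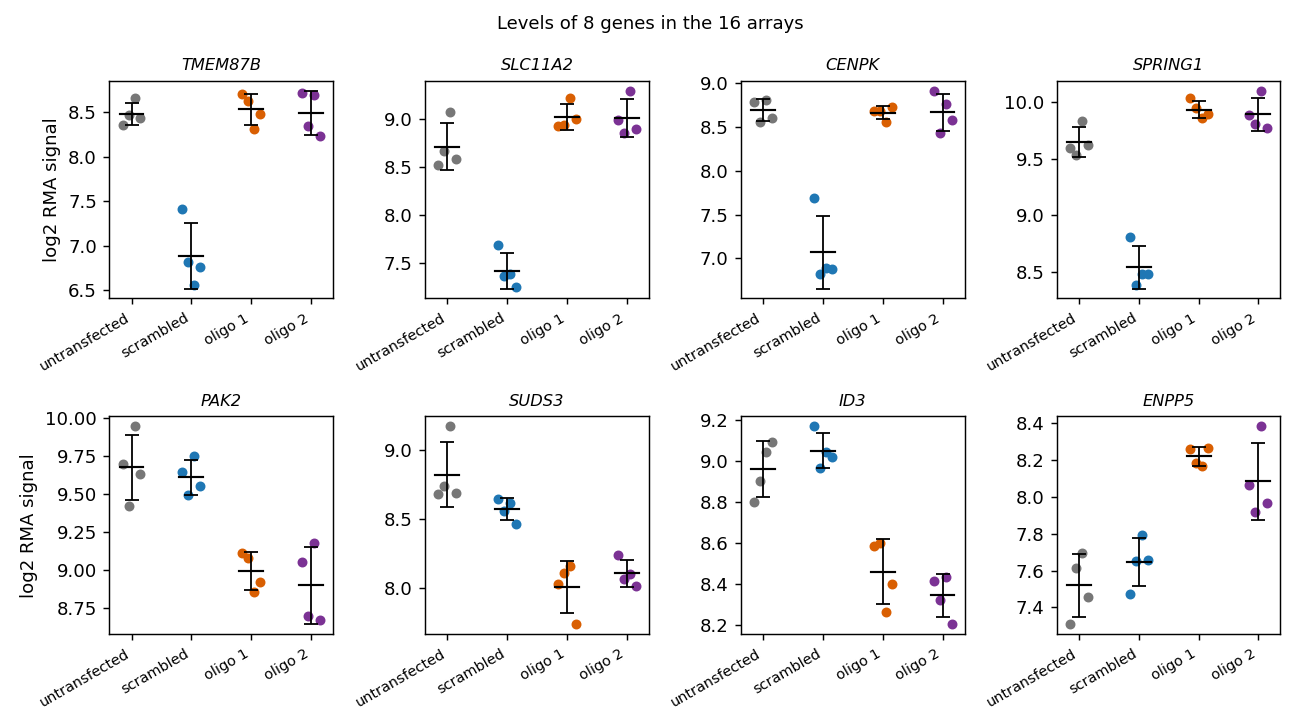
Signal (log2, vertical axes, each with its own range) of 8 genes on each array by group (horizontal axes), with points for arrays and lines with bars for means ± SD of 4 arrays. In the upper row (TMEM87B, SLC11A2, CENPK and SPRING1) the scrambled arrays lie below the other 3 groups, and in the lower row (PAK2, SUDS3, ID3 and ENPP5) both oligos lie apart from both controls.

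Gene lists were then compared between oligo and scrambled arrays. In the glycerolipid synthesis list of 34 measured genes, besides GPAM, oligo 1 lowered the lysophospholipid acyltransferase gene MBOAT1 (-0.75, adjusted p = 0.0168) and raised LPGAT1 (0.52, adjusted p = 0.0251), and oligo 2 lowered the acyltransferase gene AGPAT5 (-0.63, adjusted p = 0.0420). The other 31 and 32 members did not pass (5 and 2 genes adjusted over the list alone), and camera found no shift of the list (adjusted p = 0.726 and 0.340). By fry the list passed downward with oligo 2 (adjusted p = 0.0352) and did not pass with GPAM left out (adjusted p = 0.521). In fatty acid synthesis, oligo 1 raised ACLY, which makes cytosolic acetyl-CoA (1.35, adjusted p = 0.000182), and the elongase gene ELOVL5 (0.67), and lowered the malic enzyme gene ME1 (-0.46), while 22 of 25 did not pass (5 past it adjusted over the list alone, list adjusted p = 0.894). With oligo 2, ACLY alone rose (1.16, list adjusted p = 0.712). ACLY was 1.47 lower in scrambled than in untransfected cells, and against untransfected cells it differed by -0.12 with oligo 1 and -0.31 with oligo 2 (adjusted p = 0.819 and 0.510). Of 19 measured cholesterol synthesis genes, 0 passed with either oligo (list adjusted p = 0.943 and 0.439). In sphingolipid metabolism the serine palmitoyltransferase gene SPTLC1 rose (0.34 and 0.33) and the ceramidase gene ACER2 fell (-0.58 and -0.57) with both oligos (list adjusted p = 0.703 and 0.520). In the unfolded protein response list, DNAJC3 (0.27), HYOU1 (0.33), DNAJB11 (0.30) and HSP90B1 (0.36), all encoding chaperones or cochaperones of the endoplasmic reticulum, rose with oligo 2, while the list did not pass (adjusted p = 0.149). Of the genes of these lists named here as changed, GPAM, ACLY, ME1 and SPTLC1 kept their calls whichever single array was left out, while MBOAT1, LPGAT1, AGPAT5, ELOVL5, ACER2, DNAJC3, HYOU1, DNAJB11 and HSP90B1 lost theirs without any of 3 to 8 of the 8 arrays in turn. With the mean of all probe sets of a gene, ELOVL5 lost its call with oligo 1, SPTLC1 with both oligos, and AGPAT5, ACER2, DNAJC3 and HSP90B1 with oligo 2. ACER2 lost its call with oligo 2 also without both oligo arrays numbered 3. Neither the luminal nor the fibroblast and immune marker list shifted with oligo 1 (adjusted p = 0.894 and 0.714), nor did the mesenchymal or the basal list (adjusted p = 0.750 and 0.621). The luminal list had a median of -0.01 and a test direction upward.

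By camera with a preset correlation, 6 of 29 lists shifted with oligo 1 and 3 with oligo 2, and 0 with either with an estimated correlation. Of 26 measured p53 targets, 8 fell and 2 rose with oligo 1 (13 adjusted over the list alone, list adjusted p = 0.0367, adjusted p = 0.857 with an estimated correlation). Among them the death receptor gene FAS (-0.81), PMAIP1 (-0.86) and SPATA18 (-0.89) fell, and TP53INP1 rose (1.16). Between untransfected and scrambled cells the list had moved up (adjusted p = 1.60e-05, adjusted p = 0.312 with an estimated correlation), with FAS 0.79 higher and TP53INP1 0.96 lower. With oligo 2, 5 fell and 1 rose, and the list did not pass (adjusted p = 0.0551). Of 30 estrogen response genes, MYC (-0.58, adjusted p = 0.00576) and SIAH2 (-0.47) fell with oligo 1 and 0 rose, with a list median of -0.29 (list adjusted p = 0.000465, adjusted p = 0.857 with an estimated correlation). In the oxidative stress list, the heme oxygenase gene HMOX1 (-1.15), GCLM (-0.53), which takes part in glutathione synthesis, and AKR1C3 (-0.80) fell with oligo 1 (3 of 23, list adjusted p = 0.0367, adjusted p = 0.857 with an estimated correlation). Of 34 S phase genes, RFC5 (0.72) and the cyclin gene CCNE2 (0.70) rose while MCM5 and POLA1 (-0.31 each) fell with oligo 1, and the list moved down (median -0.14, adjusted p = 0.0361, adjusted p = 0.857 with an estimated correlation). HMOX1 had risen (1.19) and RFC5 (-0.78) and CCNE2 (-0.50) had fallen between untransfected and scrambled cells. Of these calls, that of HMOX1 was lost without scrambled replicate 3, that of CCNE2 without any of 6 of the 8 arrays in turn, and that of RFC5 with the mean of all probe sets. The cytosolic ribosome list moved down with both oligos (medians -0.08 and -0.07, adjusted p = 0.00844 and 0.0119, adjusted p = 0.857 and 0.844 with an estimated correlation), where RPS12 alone passed by itself, with oligo 1. The histone list moved up with oligo 1 (adjusted p = 0.0367, adjusted p = 0.857 with an estimated correlation), with 0 of 15 members past the threshold, also when adjusted over the list alone. With oligo 2 the hypoxia and glycolysis list (median 0.19, adjusted p = 0.0182), of which 0 members passed, and the G2/M list (median 0.08, adjusted p = 0.0260), with NEK2 (0.38) as its only member past the threshold, moved up (adjusted p = 0.844 for each with an estimated correlation). Without dim probe sets 2 lists kept their calls with oligo 1 and 1 with oligo 2. The p53, S phase and oxidative stress lists (adjusted p = 0.0627 each) and the histone list (adjusted p = 0.0561) lost theirs with oligo 1, as did the hypoxia and glycolysis (adjusted p = 0.0699) and G2/M lists (adjusted p = 0.0796) with oligo 2. In some of these lists more members passed without both oligo arrays numbered 3. Histone genes then went in opposite directions: 9 of 15 were higher with oligo 1 (list adjusted p = 2.08e-09, adjusted p = 0.197 with an estimated correlation), and 3 were lower with oligo 2 (list adjusted p = 5.87e-05, adjusted p = 0.593 with an estimated correlation). With oligo 1, 8 estrogen response genes were then lower and 1 higher (list adjusted p = 7.89e-05), 9 S phase genes lower and 2 higher (list adjusted p = 0.000175), and 6 oxidative stress genes lower (list adjusted p = 0.00518). Each of these 3 lists had an adjusted p = 0.472 with an estimated correlation. Of the G2/M genes 4 were then higher with oligo 2 (list adjusted p = 0.00636, adjusted p = 0.846 with an estimated correlation). Calls were lost without any of 2 to 8 of the 8 arrays in turn for PMAIP1, SPATA18, SIAH2, AKR1C3, MCM5, POLA1, RPS12 and NEK2, and with the mean of all probe sets for AKR1C3, MCM5, RPS12 and NEK2. Other splits of the same arrays shifted up to 11 and 9 lists. With oligo 1 the number was 2, 2 and 3 without scrambled replicate 1, oligo 1 replicate 2 or scrambled replicate 4, and with oligo 2 it was 5 without scrambled or oligo 2 replicate 3 and 1 without scrambled replicate 4. With the replicate block the histone list lost its call (adjusted p = 0.0676) and 5 lists shifted with oligo 2.

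The oligos were also compared with each other. No gene passed the threshold in limma: 0 of 19775 were called, with 651 at an unadjusted p under 0.05, and the block on replicate number also gave 0. By camera 7 lists differed, and 0 with an estimated correlation (adjusted p = 0.738 for each of the 7). Histone genes (15 measured, median 0.30, adjusted p = 8.80e-06) and oxidative phosphorylation genes (median 0.05, adjusted p = 0.00225) were higher with oligo 1. S phase genes (median -0.09, adjusted p = 0.000105), G2/M genes (-0.09, adjusted p = 0.000955), estrogen response genes (-0.19, adjusted p = 0.000955), hypoxia and glycolysis genes (-0.15, adjusted p = 0.0124) and unfolded protein response genes (-0.08, adjusted p = 0.0145) were lower. None of their members passed, also when adjusted over each list alone. Other splits of the 8 arrays shifted up to 12 lists. The call of 0 genes depended on the arrays labelled replicate 3: without both of them 744 genes were higher and 688 lower with oligo 1, while leaving out any single oligo array gave 0. Of the 7 lists, hypoxia and glycolysis lost its call without both arrays (adjusted p = 0.105). The fatty acid oxidation list then gained a call by camera, higher with oligo 1 (adjusted p = 0.0150, adjusted p = 0.252 with an estimated correlation). Of its 29 measured genes 4 were higher and 1 lower. The number of lists was 3 without oligo 2 replicate 1 and 2 without oligo 1 replicate 4.

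The scrambled siRNA was compared with untransfected cells, titled full media control in the labels, to find what differed between the controls. No mock transfection was among the groups, so effects of the reagent or the medium cannot be told from those of the siRNA. The largest rises were in the interferon-inducible gene SAMD9 (3.38-fold, log2 fold change 1.76, SE 0.36, adjusted p = 0.0152), the osteoprotegerin gene TNFRSF11B (2.80-fold), the ectonucleotidase gene NT5E (2.70-fold), HMOX1 (2.29-fold), SEMA6D (2.20-fold), CHIC1 (1.99-fold), TENT5C (1.88-fold), GAD1 (1.82-fold), BEX5 (1.77-fold) and PLAC8 (1.73-fold). Lower were CENPK (3.06-fold, log2 fold change -1.62, SE 0.16, adjusted p = 4.24e-05), TMEM87B (3.01-fold), ACLY (2.77-fold), the prolactin receptor gene PRLR (2.67-fold), C5orf24 (2.47-fold), SLC11A2 (2.45-fold), TMEM65 (2.41-fold), HOMER1 (2.39-fold), and PLEKHA1 and ELK4 (2.32-fold each). There were 135 higher and 302 lower genes, 437 in all, of which 39 had a log2 fold change of 1 or more. The excess of lower genes depended on the setting: array weights gave 460 higher and 527 lower, and leaving out the oligo arrays numbered 3 and untransfected replicate 3 gave 349 higher and 344 lower. The count was 849 with the replicate block (338 higher, 511 lower) and 222, 191 and 236 without scrambled replicate 2, 3 or 4, and without untransfected replicate 3 it was 134 higher and 197 lower. Untransfected replicate 3 stood apart in the difference between 5' and 3' probe sets of the control genes ACTB (-2.04, other arrays -0.29 to -0.11) and GAPDH (-1.46, other arrays 0.07 to 0.21). Calls were lost without single arrays for SAMD9 (scrambled replicate 2, untransfected replicate 3 or 4), HMOX1 and PRLR (scrambled replicate 3), GAD1 (untransfected or scrambled replicate 3), and TENT5C and BEX5 (7 of 8 arrays in turn). With the mean of all probe sets of a gene, TNFRSF11B, PRLR, TENT5C, GAD1, BEX5 and ELK4 lost theirs.

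Of the gene lists, 6 shifted between the controls. The interferon list moved up (41 measured, median 0.26, adjusted p = 1.84e-06, adjusted p = 0.437 with an estimated correlation), with SAMD9 as its only member past the threshold (2 adjusted over the list alone) and IFIH1 at 0.60 (adjusted p = 0.0683). Among p53 targets SESN1 (0.51), FAS (0.79) and MDM2 (0.37) rose and TP53INP1 fell (-0.96), with 13 of 26 adjusted over the list alone (list adjusted p = 1.60e-05, adjusted p = 0.312 with an estimated correlation). In the amino acid response list the serine synthesis genes PHGDH (-0.55) and PSPH (-0.40) fell (list adjusted p = 0.000938, adjusted p = 0.521 with an estimated correlation). In fatty acid synthesis ACLY (-1.47) and the desaturase gene SCD (-0.39) fell (list adjusted p = 0.0365, adjusted p = 0.312 with an estimated correlation). The oxidative stress list moved up (HMOX1 1.19, list adjusted p = 0.0328, adjusted p = 0.4999 with an estimated correlation), as did the cytosolic ribosome list (median 0.04, list adjusted p = 0.0169, adjusted p = 0.535 with an estimated correlation), of which 0 members passed. FAS, MDM2, PHGDH, PSPH and SCD lost their calls without any of 4 to 7 of the 8 arrays in turn, and MDM2, PSPH and SCD with the mean of all probe sets. The oxidative stress list (adjusted p = 0.380) and the fatty acid synthesis list (adjusted p = 0.0636) lost their calls without untransfected replicate 3. Other splits of the 8 arrays shifted up to 10 lists.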

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

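All tests weighed in this part were chosen after the results they measure had been seen, except the list tests by camera, which were planned, and the counts over other splits of the arrays, which followed a fixed rule whose outcomes were also written down afterwards.

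The arrays labelled oligo 1 replicate 3 and oligo 2 replicate 3 lay with the arrays of the other oligo. Without both arrays, 1432 genes differed between the oligos, and between the 2 arrays themselves 1421 of these (99.2%) differed in the opposite direction, so that exchanged labels may account for the pattern. Lower quality of the 2 arrays is argued against by the slope of their difference on that of the other arrays, which was -0.96, where noise alone would leave it between 0 and 1. An exchange at any step from culture to array would give the same values, and the siRNA in each tube was not measured, since the GPAM levels of the oligo groups overlap. Of the 35 splits of the 8 oligo arrays, all 35 gave at least the real count of 0 genes, as any split must, so this count says nothing about chance. The highest other, 2436 genes, was the split that exchanges the arrays numbered 3. This points to a structure of the samples, on the same values that showed the pattern.

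For many genes changed by both oligos, the level of untransfected cells lay nearer to the oligo arrays than to the scrambled arrays. With the genes chosen on 2 scrambled arrays and measured on the other 2, the lowest median change over 6 splits was 0.54 (log2), which argues against chance values of the shared scrambled arrays. The same oligo arrays served to choose the genes and to measure the change. Its size therefore keeps that selection, and chance values of the oligo arrays are not covered. Over the 99 to 311 genes so chosen, the median change of the untransfected arrays was a share of 0.666 to 0.754 of the median change of the oligo arrays. This argues against GPAM silencing having moved these genes, as a whole, away from the level of both controls. In 74.9% to 79.8% of these genes the untransfected level lay nearer to the oligo arrays than to the held-out scrambled arrays. The mean share of 0.710 is consistent with an effect of the scrambled siRNA that the oligos lack. A response to transfection that GPAM silencing turned back would give the same values and was not tested, since no other control siRNA was measured.

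Untransfected replicate 3 stood apart from the other 15 arrays, with the lowest median correlation to them (0.982, others 0.990 to 0.993). The bacterial transcripts added to the RNA had a mean 5' minus 3' difference of -2.14 on it (log2, others -1.15 to -0.65), so that shorter labelled RNA is a candidate explanation. The hybridisation controls read 10.65 (others 10.02 to 10.60). Quantile normalization removes a weaker signal of a whole array, so these values cannot tell whether its hybridisation was weaker. A different state of the cells alone is argued against by the gap of -0.99 between its added transcripts and the lowest other array, since these do not come from the cells. Whether the cells of this replicate also differed was not tested.

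A sample far from the others was sought in each group of 4 arrays, by its gap to the nearest array divided by the range of the group. Chance alone gives such a value in about 1 in 20 groups. Among array measures, 6 of 20 groups had one. In untransfected replicate 3 these were the 5' minus 3' differences of ACTB (0.907), GAPDH (0.953) and the added transcripts (0.948), and the hybridisation controls (0.864). The hybridisation controls also set apart oligo 1 replicate 4 (0.840, at 10.5) and oligo 2 replicate 2 (0.912, at 10.02).

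Among 121 genes named in the text, 47 of 484 groups held such an array, and some of these genes were named because they differed between the oligos without the arrays numbered 3. The array labelled oligo 1 replicate 3 was set apart for ADCY9 (0.975), C5orf24 (0.912), CA12 (0.928), DNAJB11 (0.841), GPAT4 (0.891), H1-2 (0.912), H2AC6 (0.858), H2AC8 (0.900), H3C2 (0.908), HIPK3 (0.905), HMOX1 (0.964), LCLAT1 (0.870), MBNL3 (0.874), NEK7 (0.884), RFC5 (0.851), TBC1D30 (0.947), TMEM38B (0.885), TTC9 (0.868) and ZDHHC4 (0.885). The array labelled oligo 2 replicate 3 was set apart for CCNE1 (0.892), GINS1 (0.963), H2AC8 (0.904), HIPK3 (0.952), PAPSS2 (0.864) and TTC9 (0.879). In the other oligo arrays these were AKR1C3 (0.892) and SLC7A11 (0.850) in oligo 1 replicate 1, PKIA (0.856) in oligo 2 replicate 1 and HS6ST2 (0.936) in oligo 2 replicate 2. Scrambled replicate 1 was set apart for C5orf24 (0.844), CENPK (0.918), ELK4 (0.863), GPAT2 (0.962), HOMER1 (0.841) and NEK2 (0.888), replicate 2 for GCLM (0.900) and HS6ST2 (0.846), and replicate 3 for AKR1C3 (0.843), GPAT4 (0.858), PAX9 (0.922) and SPINK7 (0.918). Untransfected arrays were set apart for SPINK7 (0.8293, replicate 1), ACER2 (0.928) and GCLM (0.870, replicate 2), HMOX1 (0.846) and SUDS3 (0.887, replicate 3) and GPX8 (0.871, replicate 4).

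Between the oligos, 7 lists differed by camera, with adjusted p = 8.80e-06 for histones, 0.000105 for S phase, 0.000955 each for G2/M and estrogen response, 0.00225 for oxidative phosphorylation, 0.0124 for hypoxia and glycolysis and 0.0145 for the unfolded protein response. With an estimated correlation 0 lists passed (lowest adjusted p = 0.738). Of 35 splits of the 8 arrays, 8 shifted as many lists, so chance cannot be excluded (real 7, highest other 12). Nor can it be excluded for the lists of oligo 1 against scrambled (7 of 35 splits, real 6, highest other 11), oligo 2 against scrambled (22 of 35, real 3, highest other 9) and scrambled against untransfected (10 of 35, real 6, highest other 10).

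For the counts of genes, only the real split among all 35 gave as many for oligo 1 against scrambled (1 of 35 splits, real 1162, highest other 1), oligo 2 against scrambled (1 of 35, real 1016, highest other 1) and scrambled against untransfected (1 of 35, real 437, highest other 0). These splits ignore the pairing of replicate numbers, so they argue only against arrays that are all interchangeable. For each of these comparisons, the 8 splits that part all 4 pairs of replicate numbers keep the pairing. They are too few for a share under 0.05 (real 1162, 1016 and 437, highest other 0 in each), so chance within the pairing cannot be excluded. The drawn assignments below ignore the pairing as well. For genes changed by both oligos, 2 of 100 assignments of the 12 arrays gave as many (real 689, highest other 834), which likewise argues only against arrays that are all interchangeable. The assignment with 834 kept the 4 scrambled arrays together as an oligo group and parted the oligos with the arrays numbered 3 exchanged. For genes changed by both oligos against both controls, 1 of 100 assignments of the 16 arrays gave as many (real 13, highest other 0). The same limit holds, and GPAM, the target of the oligos, is among the 13.

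Probe sets without a single gene symbol, which no comparison of genes used, also held changes: of 13522 tested (56 controls left out), 125 passed for oligo 1 against scrambled, 94 for oligo 2 against scrambled, and 58 for scrambled against untransfected.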

How the results depend on the processing

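Leaving out arrays in doubt, averaging the oligos and leaving GPAM out of its list were chosen after the data had been seen, and all other alternatives before. Of 239 values tried under other settings, 167 stayed on their side of the threshold or within 1.5 times, 72 moved and 0 reversed. Counts of genes or lists, which are among these values, cannot reverse. The fold change of GPAM kept its direction and threshold in each, from -2.86 to -2.47, with a highest adjusted p of 2.31e-05. For 156 pairs of a named gene and a comparison, 1572 of 1869 values kept direction and threshold, 297 lost the threshold (256 without a single array, 37 with the mean of all probe sets of a gene and 4 without the oligo arrays numbered 3) and 0 reversed. Where the arrays of the groups compared do not overlap, leaving out an array cannot reverse a gene. The cause was not tested for the changes below, except where stated.

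With the replicate number as a block, 1822 genes changed with oligo 1 against scrambled, 1672 with oligo 2, 849 between the controls and 1155 with both oligos, and 5 lists shifted with oligo 2. The block removes differences that replicates of the same number share, and it ended the call of 0 named genes. Of 16 arrays 14 correlated best with an array of the same number in another group, all but oligo 1 replicate 3 and oligo 2 replicate 3, a hint from the data and not the design. The histone list lost its call with oligo 1 (adjusted p = 0.0676). Array weights gave 2979, 2213, 987 and 1282 genes. Each probe set by itself gave 767 between the controls. A log2 fold change of 1 or more left 78, 65, 39 and 41 genes, and an adjusted p under 0.01 left 416, 337, 167 and 249, as stricter thresholds must. With untransfected cells as the control, 38 genes changed with oligo 1 (314 with the replicate block), 25 with oligo 2 (202) and 15 with both, and 13 changed against both controls.

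Without the oligo arrays numbered 3, 1915 genes changed with oligo 1, 1553 with oligo 2 and 1432 between the oligos, and 5 lists shifted with oligo 2. Without untransfected replicate 3 as well, the numbers were 2658, 2268 and 2020, and 693 between the controls. The mean of both oligos changed 1667 genes against scrambled, 140 against untransfected and 92 against both.

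Leaving out single arrays of the groups compared gave 578 to 1475 genes for oligo 1, 424 to 1236 for oligo 2, 322 to 659 for both, 191 to 406 between the controls, and 2 to 7, 1 to 5, 2 to 9 and 4 to 7 lists for oligo 1, oligo 2, the oligos against each other and the controls. With fewer arrays the test has less power. Arrays of other groups enter through the variance: without untransfected replicate 3 the oligos gave 1530, 1384 and 943 genes, and without oligo 2 replicate 3 the controls gave 502. With an estimated correlation 0, 0, 0 and 0 lists shifted, and by fry 0, 3, 0 and 3 (0, 2, 0 and 3 with GPAM left out). By fry these were the glycerolipid synthesis, lipid droplet and cytosolic ribosome lists with oligo 2, the first of which lost its call without GPAM, and the fatty acid synthesis, p53 and autophagy lists between the controls. Without dim probe sets 2 lists shifted with oligo 1 and 1 with oligo 2. The covariance of fold changes between the oligos (0.0390) was 0.0125 with separate controls for each oligo and 0.0534 without dim probe sets. Signals near the background, where RMA compresses changes, limit what can be seen for dim genes.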

Other observations

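All tests in this part were chosen after the data had been seen. Without the arrays labelled oligo 1 replicate 3 and oligo 2 replicate 3, which leaves 3 arrays per oligo, 744 genes were higher and 688 lower with oligo 1 than with oligo 2. Of 15 measured histone genes 10 were higher with oligo 1 and 0 lower (11 adjusted over the list alone, median 0.67, list adjusted p = 4.39e-17, adjusted p = 0.0291 with an estimated correlation), among them H3C2 (2.24), H2BC4 (1.65), H2AC6 (1.39), H2AC8 (1.38) and H1-2 (1.10). Of 34 S phase genes 7 were lower, with the ribonucleotide reductase gene RRM2 (-0.81), GINS1 (-0.73), UHRF1 (-0.62) and CCNE1 (-0.45) leading (list adjusted p = 4.03e-06, adjusted p = 0.255 with an estimated correlation). Of 30 estrogen response genes 7 were lower, such as the carbonic anhydrase gene CA12 (-0.71), and 2 higher, such as ADCY9 (1.24), with a list adjusted p = 2.87e-05 (adjusted p = 0.428 with an estimated correlation). In glycerolipid synthesis LCLAT1 (0.76), GPD1L (0.78) and CDS1 (0.59) were among 6 higher genes and PLPP1 (-0.74) among 4 lower ones (list adjusted p = 0.322). GPAT3 was lower with oligo 1 (-1.13, SE 0.25, adjusted p = 0.0111), while GPAM differed by -0.13 (adjusted p = 0.797). The sulfate transporter gene SLC26A2 (-1.74), the sulfate-activating enzyme gene PAPSS2 (-1.78) and MBNL3 (-1.47) were lower with oligo 1, and ZDHHC4 (1.57) and TMEM38B (1.52) were higher.

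The mean of both oligos, on 8 arrays, differed from scrambled and from untransfected cells in the same direction for 92 genes, 34 higher and 58 lower. Beside GPAM, the lower genes included POLR3G (-1.14 against scrambled and -0.99 against untransfected), IL1RAP (-1.22 and -0.99), PAX9 (-1.26 and -0.87), the cystine transporter gene SLC7A11 (-0.77 and -1.22) and the Wnt inhibitor gene DKK1 (-0.80 and -0.63). The higher ones included the gp130 receptor gene IL6ST (0.95 and 0.68), PKIA, an inhibitor of protein kinase A (0.93 and 0.67), STRADB (1.03 and 0.64) and the collagen gene COL5A1 (0.88 and 0.58). These genes were named after their values were seen. Against untransfected cells POLR3G (limma adjusted p = 0.0475) and COL5A1 (adjusted p = 0.0441) lay close to the threshold. With the mean of all probe sets of a gene, COL5A1 lost its call against scrambled cells with oligo 1, and IL1RAP with oligo 2.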
